A study of Homo sapiens with 9 samples.

How the data were processed

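The series holds 9 human samples, of which 7 had a peak list analysed here and 2, the inputs of primary hepatocytes and of H1 cells, had none and were not analysed here. Soluble chromatin was immunoprecipitated with an antibody against H3K27ac and sequenced as paired reads on an Illumina instrument, per the labels' protocols. Bowtie and the human genome build hg38 were used, per the submitters' processing notes, which give no version. The peak caller, its control and its threshold were not given in the sources used here. Each deposited peak list has 5 columns and belongs to 1 library, so peaks were called per library and not on pooled samples. The only value per peak is a whole-number score that the authors deposited, with a lowest value of 90 to 92 in each list. The scale of this score was not stated. It is the authors' own value for each peak and was used only to rank or filter peaks within a list.

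Samples were grouped by their labels as primary hepatocytes (n = 2), 2D hepatocyte-like cells (n = 2), 3D S4, 3D S5 and H1 cells (n = 1 each). The labels do not state whether the 2D libraries came from separate differentiations, so p-values measure only the spread between these libraries. The run tag in the titles was shared by the primary, 2D and S5 libraries and differed for S4, and H1 had none. Chromosome Y, the XIST region and unplaced sequences were removed before any analysis.

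List lengths differed between libraries and depth was unknown, so peaks were ranked by score and each list was shortened to the covered length of the shortest list compared. This was 38.5 Mb over the 6 hepatocyte libraries and 10.2 Mb with H1. At 38.5 Mb the lowest score kept was 208 and 91 in the primary, 605 and 415 in the 2D, 471 in the S4 and 424 in the S5 library. Weaker peaks were therefore dropped from the 2D and 3D lists at scores that were kept in the primary lists. Overlapping peaks were merged into regions across libraries, and a region counted as called in a library with at least 1 bp of overlap. Chance overlap came from 100 circular shifts of the peaks. Intervals on shares are 95% Wilson intervals and cover counting error only.

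Genes came from the RefSeq annotation of GRCh38.p14, the same build as hg38, and coordinates are 1-based. A locus was the gene span with 25 kb on each side, since the table gives no strand and no transcription start could be assigned. A gene end was called with a peak within 1 kb of either end of the gene. Protein-coding and listed genes gave 19975 loci, and 88.8% of them overlapped another locus, so neighbouring genes often share peaks. The covered kb per locus was tested as log2(kb + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a trend, Benjamini-Hochberg, threshold 0.05), over loci with cover in at least 2 of the 4 libraries compared. Differences on this scale understate the change of loci with little cover, and no fold is given where a group had no peak. The spread was estimated from 2 residual degrees of freedom per gene with trend moderation. All 823 loci called between primary and 2D libraries had libraries that did not overlap, as did 59.9% of all loci tested, against 33.3% by chance. On simulated data for that comparison (17007 loci), limma recovered 72.0% of loci changed by 2 and 6.00% of loci changed by 1 on the log2 scale, with 5 false calls. For 3D against 2D (16706 loci) it recovered 50.0% and 0%, with 1 false call. Simulated loci varied independently and normally with the fitted spread, whereas real neighbouring loci share peaks. The false calls in the simulation therefore do not tell how many of the real calls are false.

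Before the data were examined, 29 gene lists with 383 genes were fixed, covering liver functions, signalling, other cell types, pluripotency and housekeeping. They were tested with camera in limma with a correlation of 0.01 and with an estimated correlation. With 1 library in a group, the list median was placed among 10000 random lists of the same size matched on mean cover, with no p-value, for up to 29 lists in each of 4 such comparisons and for the 2D libraries against each other. Named genes were 12 followed in every case (ALB, AFP, HNF4A, CYP3A4, CYP3A7, CYP7A1, THRA, THRB, POU5F1, NANOG, SOX2 and GAPDH), up to 4 members per list with the largest differences, and the 8 highest and 8 lowest loci of each comparison, among those past the threshold with no overlap between groups or, failing that, by size alone. A gene named outside this rule is given as such.

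Alternatives were lists as deposited, equal numbers of peaks, coverage of at least 50% of a region, 500-bp bins, scaling to the total covered length, flanks of 5 and 100 kb, a pseudocount of 0.2 kb, no filter, all 7 libraries in one fit, and each replicate left out in turn. A planned threshold on q could not be applied, since the lists hold no q, and a score of at least 200 was used in its place, chosen after seeing the data. The planned ranking by p used the score instead, loci around transcription starts became gene spans, and calls at any transcription start became calls in the gene body. A planned motif comparison was not run because no genome sequence was used here. Counts of regions have no p-value, because 4 libraries can be split into pairs in only 3 ways. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for intervals and matplotlib 3.10.9 for plots.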

Results

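Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in human hepatocytes and in hepatocyte-like cells made from pluripotent stem cells. Peak lists were analysed for 7 libraries: 2 of primary human hepatocytes, 2 of hepatocyte-like cells grown as flat (2D) cultures, 1 each of the 3D spheroid cultures S4 and S5, and 1 of H1, an established human embryonic stem cell line. The labels do not say what S4 and S5 stand for. The lists held 47495 and 40300 peaks in the primary libraries, 78994 and 121135 in the 2D libraries, 83100 in S4, 55561 in S5 and 29310 in H1. They covered 42.3 and 38.5 Mb, 57.7 and 80.2 Mb, 54.6 Mb, 46.5 Mb and 10.2 Mb, respectively. The H1 peaks were the narrowest, with a median width of 268 bp against 393 to 650 bp elsewhere. Sequencing depth was unknown from the peak lists, so all lists compared were first shortened to the same covered length, strongest peaks first. Below, a locus with no peak had none left after this step, and a weaker deposited peak may have been dropped.

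The first question was how far the acetylated regions of the cultured cells overlapped those of primary hepatocytes. The primary libraries shared most with each other, with a Jaccard index (shared bases over all covered bases) of 0.767. The 2D libraries reached 0.504 with each other and 0.423 to 0.478 with the primary libraries. S5 overlapped the 2D libraries at 0.578 and 0.571 and the primary libraries at 0.492 and 0.496. S4 overlapped the primary libraries at 0.343 and 0.352, below every 2D and S5 value. Peaks moved to random positions gave mean indices of at most 0.00938. There was 1 value per pair and so no test.

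**Figure D1:**
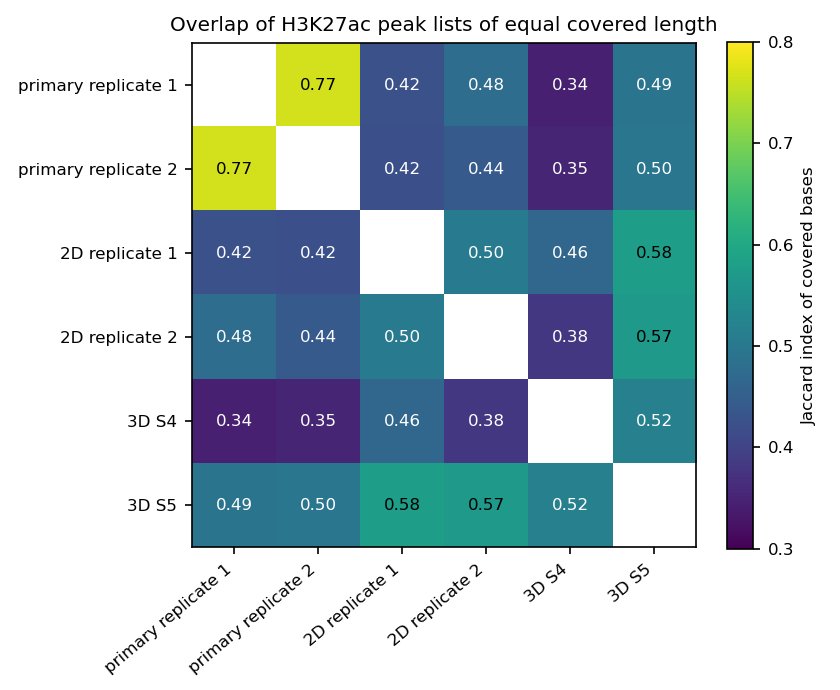
Jaccard index of covered bases for each pair of the 6 hepatocyte libraries, with lists of equal covered length; both axes list the libraries and the colour scale runs from 0.3 to 0.8. The primary pair has 0.767, the 2D pair 0.504, and S4 with the primary libraries 0.343 and 0.352.

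Primary hepatocytes and 2D cells differed at many regions away from annotated gene ends. Over these 4 libraries there were 61430 regions, of which 16172 were called in all 4. A further 9695 regions were called in both primary libraries and neither 2D library, and 3605 in both 2D libraries and neither primary library. The other splits of the 4 libraries into pairs gave 263 and 452, and 949 and 707, regions. Only 19.3% of the primary-only and 22.6% of the 2D-only regions lay within 2 kb of an annotated gene end, against 68.2% of the regions shared by all 4. The shared regions were wider, with a median of 1488 bp against 585 and 944 bp, and so reach a gene end more easily. A further 57.0% of the primary-only and 42.2% of the 2D-only regions lay in gene bodies, where transcription starts could not be placed. The longest primary-only region, 9232 bp on chromosome 11 from 2152113 to 2161344 (hg38), overlapped INS and INS-IGF2. The longest 2D-only region, 14753 bp on chromosome 19 from 950350 to 965102, overlapped ARID3A, a DNA-binding factor. The balance of the counts turned with the lists as deposited, where 3158 regions were primary-only and 18917 were 2D-only. With 500-bp bins in place of regions the counts were 17339 and 9905. With 1 library left out, primary-only regions reached 15667 and 2D-only regions 12729. Fewer libraries loosen the definition of both classes, so this rise does not measure dependence on 1 library.

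Single genes of drug oxidation and plasma proteins carried more H3K27ac in primary hepatocytes, and single bile-duct and fetal-liver genes more in 2D cells. At CYP2D6, a drug-oxidising cytochrome P450 on chromosome 22 from 42126499 to 42130810, peaks covered 16.7 ± 1.24 kb in primary hepatocytes and 0.309 ± 0.438 kb in 2D cells (SD, n = 2 each; log2 difference 3.80 ± 0.29 SE, adjusted p = 0.0333). At ITIH4, a secreted plasma protein on chromosome 3 from 52812962 to 52830672, the cover was 28.9 ± 7.29 kb against 2.15 ± 0.0099 kb (log2 difference 3.23 ± 0.22, adjusted p = 0.0329). KRT19, a keratin of bile-duct cells on chromosome 17 from 41523617 to 41528308, had no peak in either primary library and 10.1 ± 1.83 kb in 2D cells (adjusted p = 0.0329). DLK1, a fetal-liver gene on chromosome 14 from 100726892 to 100738224, had no primary peak and 6.97 ± 2.88 kb in 2D cells (adjusted p = 0.0397). Of 17008 loci tested with limma, 346 were higher and 477 lower in primary hepatocytes, and 4461 had an unadjusted p under 0.05. The other splits of these 4 libraries into pairs gave 0 calls in limma, with 45 and 303 loci at an unadjusted p under 0.05. In those splits the difference between primary and 2D libraries counted as spread, so few calls were likely in advance. Their counts do not tell how many of the calls between primary and 2D libraries are false.

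Among all loci past the threshold, the highest were CYP2D6, the carboxylesterase gene CES3, MUSTN1 and its neighbour ITIH4, KLHL25, the complement gene C4B and its neighbour CYP21A2, and CTRC, a pancreatic protease gene. CES3 had 9.30 ± 0.65 kb and CTRC 6.13 ± 0.872 kb in primary hepatocytes, with no peak left in either shortened 2D list (adjusted p = 0.0329 for both). KLHL25 had 18.8 ± 2.31 kb against 1.37 ± 0.426 kb, a log2 difference of 3.07 ± 0.20. MUSTN1 (log2 difference 3.25), C4B (3.04) and CYP21A2 (2.77) passed with adjusted p of 0.0471, 0.0362 and 0.034. C4B, CYP21A2 and CYP2D6 lie beside near-identical copies, so the place of their reads was uncertain. Among the lowest were the heart and gut endoderm factor GATA5, PXDN, DSCAML1, DNAH17, KAZN, the procollagen peptidase ADAMTS2 and the matrix protein SMOC2. GATA5 had 0.233 ± 0.33 kb in primary hepatocytes and 22.4 ± 4.26 kb in 2D cells, a log2 difference of -4.26 ± 0.27. DNAH17 differed by -3.77 ± 0.41. The other 5 of these loci had no peak in either primary library and between 11.7 ± 5.02 kb (SMOC2) and 15.3 ± 0.707 kb (PXDN) in 2D cells.

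Metabolic lists fixed beforehand mostly lay higher in primary hepatocytes. Of 11 tested genes for drug oxidation, 4 rose, none fell and 7 did not pass, and 6 rose when adjusted over the list alone. CYP2E1 had 5.62 ± 0.652 kb and CYP4F2 1.83 ± 0.204 kb in primary hepatocytes, with no peak in 2D cells (adjusted p = 0.0329 for both). The camera test of the list gave an adjusted p of 0.000332 with its preset correlation, and adjusted p = 0.51 with an estimated correlation. Of 11 fatty acid oxidation genes, 2 rose, among them CYP4A11, and 9 did not pass, with 5 higher when adjusted over the list alone. The list had adjusted p = 0.00801, and adjusted p = 0.51 with an estimated correlation. In the plasma protein list of 20 tested genes, 5 rose: ITIH4, its neighbours ITIH3 (log2 difference 2.17) and ITIH1 (1.79), and the adjacent ORM1 (1.94) and ORM2 (1.85). HPX fell (-1.15), and 14 did not pass. ITIH1 and HPX were named after their values were seen. Adjusted over the list alone, 7 rose and 1 fell. The list had adjusted p = 0.00994, and adjusted p = 0.577 with an estimated correlation. Neighbouring loci such as the ITIH genes, or ORM1 and ORM2, can count the same peaks. The counts and test of the plasma protein list therefore do not rest on independent genes.

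A further 7 lists passed upward with the preset correlation although no single member passed over all genes. These were coagulation (adjusted p = 0.00116), acute phase, complement and urea and amino acid metabolism (0.00994 each), glucose and sterol and fat synthesis (0.0197 each) and hepatocyte transcription factors (0.022). None passed with an estimated correlation (adjusted p = 0.51 for coagulation, glucose, urea and hepatocyte factors, and adjusted p = 0.537 for the other lists). Adjusted over the list alone, 4 of 7 acute phase genes, 6 of 13 urea and amino acid genes, 2 of 13 complement genes and 2 of 15 hepatocyte factors were higher, and 1 urea and amino acid gene was lower. The median log2 difference was 1.27 for the acute phase list and 0.69 for the urea and amino acid list. The acute phase genes with the largest differences, SAA2, SAA1 and SAA4, are neighbours on chromosome 11 with overlapping loci. They can count the same peaks, so the acute phase counts, median and list test do not rest on independent genes. PCK1, the rate-limiting enzyme of gluconeogenesis, had 14.1 ± 2.65 kb in primary hepatocytes and 1.64 ± 1.23 kb in 2D cells (adjusted p = 0.063). RXRA, a partner of many nuclear receptors, had 119 ± 0.978 kb and 41.0 ± 11 kb (adjusted p = 0.0598). Among bile acid and transport genes, 1 of 16 rose (ABCB11, named after its value was seen), AKR1D1 fell, and 5 were higher and 1 lower adjusted over the list alone; the list did not pass (adjusted p = 0.0604).

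Lists of bile-duct, mesenchymal, intestinal and fetal-liver genes lay lower in primary hepatocytes with the preset correlation. Of 12 bile-duct genes, 3 fell: KRT19, CLDN4 (1.75 ± 0.0177 kb against 6.53 ± 0.362 kb) and CFTR (log2 difference -0.81, named after its value was seen), and 5 fell when adjusted over the list alone. The list had adjusted p = 0.000185, and adjusted p = 0.51 with an estimated correlation. Of 10 fetal-liver genes, DLK1, the RNA-binding protein genes IGF2BP1 (log2 difference -2.37) and LIN28B, and the imprinted H19 (-1.79) fell, and 6 did not pass. Adjusted over the list alone, 6 fell, and the list had adjusted p = 0.000556, and adjusted p = 0.537 with an estimated correlation. The stellate and mesenchymal list (adjusted p = 0.0197) had no member that passed over all genes and 1 lower when adjusted over the list alone. The intestine list (adjusted p = 0.0472) had 1, ISX, and 3 adjusted over the list alone. With an estimated correlation they had adjusted p = 0.577 and adjusted p = 0.51. The endothelial factor ERG had no primary peak and 1.81 ± 0.142 kb in 2D cells, and the receptor KDR had none and 1.36 ± 0.163 kb (adjusted p = 0.0329 and 0.0333). Both fell, but the endothelial list did not pass (adjusted p = 0.119). CD3E, CD3D, TUBB3 and GRIN1 also fell, while their lymphoid (adjusted p = 0.339) and neural (adjusted p = 0.293) lists did not pass. Adjusted over the list alone, 1 endothelial gene, VWF (5.68 ± 1.31 kb against 2.45 ± 0.0735 kb), and 2 lymphoid genes, among them GNLY (3.48 ± 0.96 kb against 0.908 ± 0.397 kb), were higher, and 3 endothelial, 3 lymphoid and 2 neural genes were lower.

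Of 15 tested pluripotency genes, POU5F1 and DPPA4 (log2 difference 1.13) rose and 13 did not pass, and adjusted over the list alone 2 rose and 2 fell. POU5F1, a pluripotency factor, had 3.56 ± 0.38 kb at its locus in primary hepatocytes and 0.896 ± 0.0636 kb in 2D cells (log2 difference 1.27, adjusted p = 0.0349). With 5-kb flanks that difference was -0.23, so the excess lay in the flanks shared with neighbouring genes. HNF4A, a master regulator of hepatocytes, had 13.8 ± 1.75 kb and 11.9 ± 5.30 kb (adjusted p = 0.708). The thyroid hormone receptor genes THRA (12.4 ± 1.45 kb against 8.28 ± 0.0806 kb) and THRB (3.02 ± 0.218 kb against 2.29 ± 0.0601 kb) had adjusted p of 0.14 and 0.195. GAPDH had 9.73 ± 1.98 kb and 7 ± 0.855 kb (adjusted p = 0.306), and SOX2 had an adjusted p of 0.959. ALB, the albumin gene, had only 0.954 ± 0.0474 kb and 0.715 ± 0.465 kb (adjusted p = 0.612). The remaining lists did not pass: AP1 and YAP targets (adjusted p = 0.894), apolipoproteins (0.202), conjugation enzymes (0.604, with 1 gene higher adjusted over the list alone), endoderm (0.104), housekeeping (0.527), hypoxia (0.822), JAK-STAT3 (0.339), myeloid (0.604), pluripotency (0.822), proliferation (0.117) and thyroid hormone (0.653, with 1 gene lower adjusted over the list alone). AFP, CYP3A4, CYP3A7, CYP7A1 and NANOG had peaks in fewer than 2 of the 4 libraries and were not tested.

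**Figure D2:**
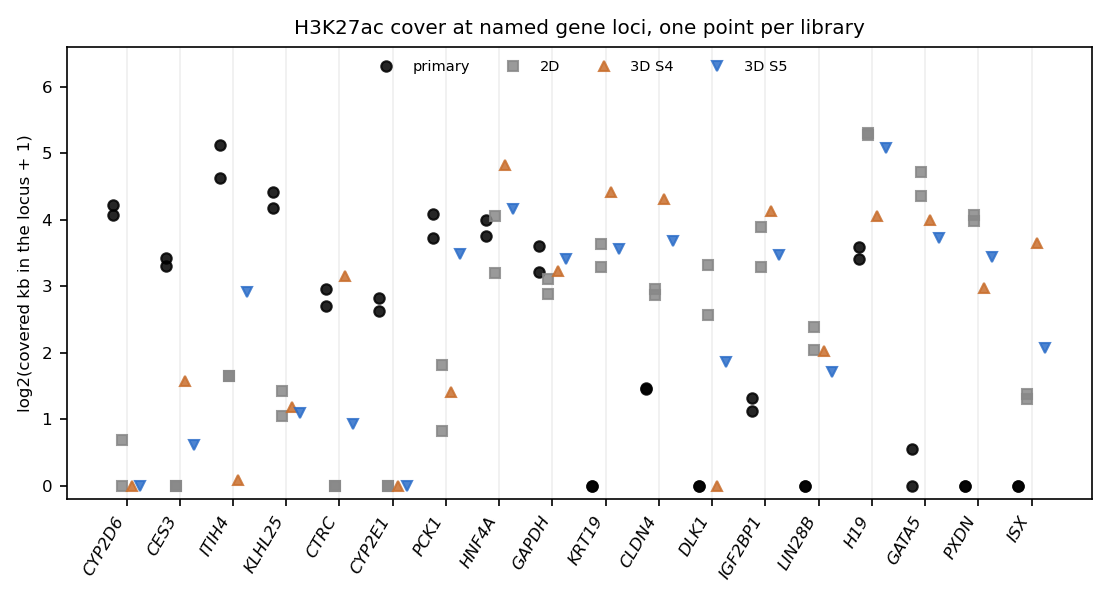
Covered length at 18 gene loci on a log2(kb + 1) scale, one point for each primary, 2D, 3D S4 and 3D S5 library. CYP2D6 has 16.7 kb in primary hepatocytes against 0.309 kb in 2D cells, and GATA5 has 0.233 kb against 22.4 kb.

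The calls depended on how list length was treated. With the lists as deposited, 3 loci were higher and 251 lower (the median of all genes moved to -0.34), and after scaling to the total covered length 33 were higher and 202 lower (median 0.20). With 1 replicate left out, a group held 1 library and the spread came from the other pair alone. The number of calls in those fits therefore cannot tell how far single libraries carried the result. The median log2 difference of all genes lay between 0.010 and 0.084 in them. All 14 lists past the preset threshold kept their direction relative to the median of all genes under both scalings.

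The share of primary regions found in the cultures was compared between 2D and 3D cells. Of 29937 regions called in both primary libraries, 57.8% and 63.3% were called in the 2D libraries (60.6% ± 3.94, SD, n = 2), 51.5% in S4 and 65.0% in S5. S4 thus lay below both 2D libraries and S5 above both. Of primary regions missing in 1 of the 2D libraries, the other called 18.9% ± 8.09 (SD over the 2 choices), S4 7.09% ± 0.911 and S5 22.4% ± 4.01. Of regions of 1 2D library called in neither primary library, the other 2D library called 31.9% ± 5.18, S4 25.2% ± 5.78 and S5 38.6% ± 3.38. The S5 values lay within 1 SD of the 2D reference for primary regions missing in 2D. With the lists as deposited, S5 lay below the 2D libraries for both primary measures, at 72.6% against 80.2% and at 24.7% against 44.4%.

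**Figure D3:**
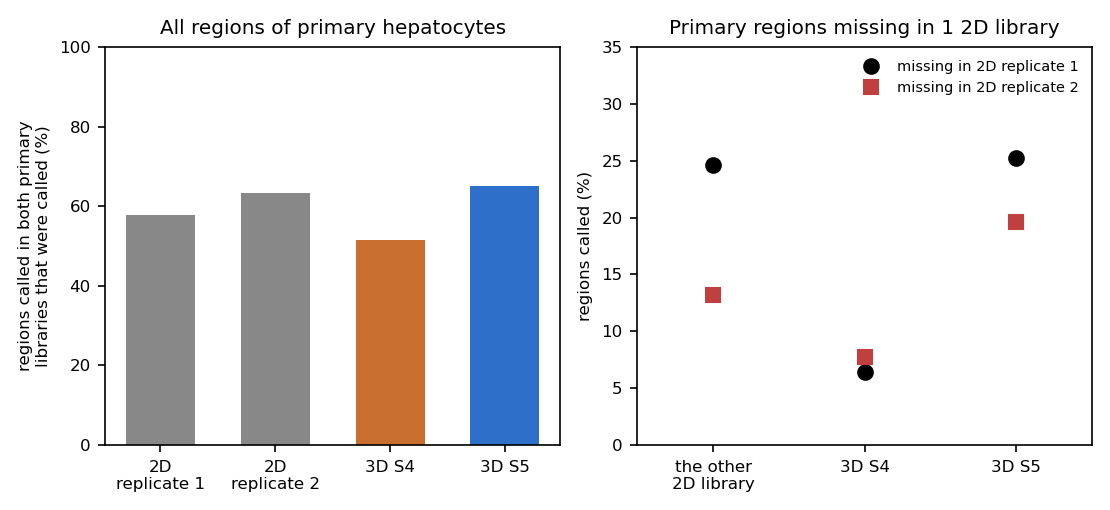
Left, bars show the percentage of the 29937 regions called in both primary libraries that each 2D or 3D library called; right, points show the percentage of primary regions missing in 1 2D library that the other 2D library, S4 and S5 called. S4 is lowest in both panels (51.5%, and 7.09% on average).

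Regions called in both 3D libraries and neither 2D library numbered 1798, and 15.2% of them were called in both primary libraries. The reverse class held 1264 regions, with 22.7% in both primary libraries. The other splits gave 884 and 2662, and 73 and 1168, regions. For S4 and S5 as a pair against the 2D libraries, limma called none of 16720 loci, with 1334 at an unadjusted p under 0.05. The other splits of these 4 libraries had 1376 and 238 such loci, with any difference between 3D and 2D cells counted as spread. In the fit of 3D against 2D, the difference between S4 and S5, separate cultures with different run tags, counted as spread. The lack of calls therefore does not show that 3D and 2D cells were alike. Without the filter on cover, 11 loci were higher in 3D cells and 19 lower. By size alone, the highest 3D loci were PLAAT2 (7.26 against 0.377 kb, log2 difference 2.51 ± 0.55), SLC6A7 (2.42 ± 0.75), TM4SF1, TMEM238L, MRPS18A, VMP1, RIMBP2 and CTRC. The lowest were PRR33 (no 3D peak, 12.6 kb in 2D cells), LOC124900164, LGALS9C, ARHGAP22 (log2 difference -2.73 ± 0.80), the gut mesenchyme factor NKX2-3, LGALS9B, LCN8 and SH3RF3. LGALS9B and LGALS9C are near-identical copies, so their reads could not be placed with certainty. No list passed with the preset correlation, the lowest adjusted p being 0.0812 for the endothelial, fatty acid oxidation and hepatocyte factor lists, and adjusted p = 0.766 with an estimated correlation. Adjusted over the list alone, 3 endothelial genes and 1 intestine gene were lower. The endothelial genes ERG and KDR, covered in both 2D libraries, had no peak in S4 or S5 (adjusted p = 0.553 for both).

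Each 3D library was then set against the 2D mean. Random lists drew genes singly, while neighbouring loci in a list can share peaks, so percentiles here and below may be too extreme. The 2D libraries set against each other already placed the acute phase (0.75) and fetal-liver (0.43) lists above the 99th percentile and the neural list (-0.80) below the 1st, so lists can pass these percentiles between replicates of 1 group. In S5 the list medians of hepatocyte factors (0.37), plasma proteins (0.34), fatty acid oxidation (0.51), urea and amino acid metabolism (0.44), apolipoproteins (0.37), glucose (0.32), coagulation (0.31) and bile-duct genes (0.28) all lay above the 99th percentile of 10000 random lists matched on cover. The intestine list lay at percentile 97.6 (0.27) and the conjugation enzyme list at percentile 97.9 (0.28). PCK1 had 10.2 kb in S5, 1.64 ± 1.23 kb in 2D cells and 1.67 kb in S4, and SDS, a serine-degrading enzyme, had 14.4, 2.53 and 5.00 kb. The metallothionein genes MT1A and MT1E, CYP26B1, a retinoic acid-degrading enzyme, GLT1D1, SDSL and SLC6A7 were the other loci with the largest S5 excess. The 2D libraries themselves differed widely at CYP26B1, so the size of its excess depended on which 2D library was used. In S4 the intestine (0.72), hypoxia (0.68), hepatocyte factor (0.53), cholangiocyte (0.48) and plasma protein (0.44) lists lay above that percentile, and the fatty acid oxidation list at percentile 98.0 (0.38). CDH17, an intestinal cadherin, had 8.29 kb in S4, 0.817 kb in S5 and 0.302 kb on average in 2D cells. KRT19 had 20.3 kb in S4 and 10.8 kb in S5, CLDN4 18.8 and 11.8 kb, and HNF4A 27.4 and 16.8 kb. In the other direction KRT7, a further bile-duct gene, had no peak in S4 and 3.02 kb in S5. Of the 12 bile-duct genes, 9 lay higher and 3 lower in S4 than in 2D cells. The endothelial list lay below the 2.5th percentile in both 3D libraries (-0.34 in S4 and -0.21 in S5), and the stellate and mesenchymal list in S4 (-0.46). The sizes of these medians depended on list length. Relative to all genes, the endothelial value moved from -0.37 to -0.79 in S4 and from -0.27 to -0.49 in S5 with the lists as deposited. In S5 coagulation moved from 0.25 to 0.54 as deposited, and plasma proteins from 0.28 to 0.17 after scaling to the total covered length.

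**Figure D4:**
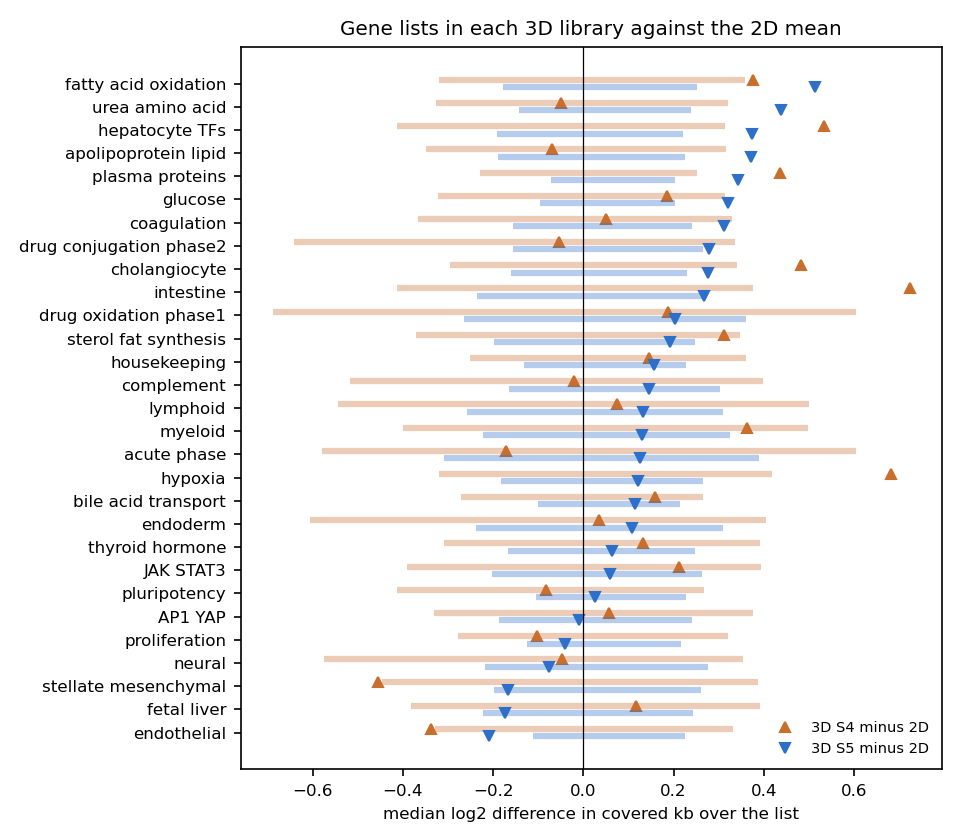
Median log2 difference in covered kb of each fixed gene list, S4 (upward triangles) and S5 (downward triangles) minus the 2D mean, with bars for the central 95% of random lists matched on cover. The intestine list is at 0.72 in S4 and 0.27 in S5, and the urea and amino acid list at -0.05 and 0.44.

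S4 and S5 shared about as much with each other (Jaccard index 0.517) as the 2D libraries did (0.504), but less at the length of the H1 list (0.486 against 0.601). Of 11190 regions called in S5 and not in S4, 37.8% were called in both primary libraries (95% Wilson interval 36.9 to 38.7%), and 35% and 48.4% in the 2D libraries. Of 11437 regions called in S4 and not in S5, 1.64% were called in both primary libraries (1.43 to 1.89%), and 8.64% and 1.55% in the 2D libraries. S5 minus S4 lay above the 99th percentile for the coagulation (0.61) and urea and amino acid (0.41) lists, and at percentile 98.7 for the apolipoprotein list (0.31). It lay below the 1st percentile for hypoxia (-0.47), intestine (-0.46) and cholangiocyte (-0.43). Relative to all genes, the apolipoprotein value shrank from 0.29 to 0.05 both with the lists as deposited and after scaling. The acute phase list had a median of 0.42 (percentile 92.5), but relative to all genes it turned to -0.23 with the lists as deposited and -0.19 after scaling. Relative to all genes, the directions of the lists above the 99th and below the 1st percentile held with the lists as deposited and after scaling. Their sizes moved: coagulation shrank from 0.59 to 0.39 and 0.37, and urea and amino acid metabolism from 0.40 to 0.22 and 0.21. Hypoxia grew from -0.49 to -0.69 and -0.67 and cholangiocyte from -0.44 to -0.58 and -0.56, while intestine stayed near -0.47. The loci with the largest excess in S4 were SULT1C2, SULT1C3, MOGAT2, SLC39A11, CDH17, CTRC, AKR1C1 and PRR5L, and in S5 they included ASPG, ONECUT2, HOXA3 and CACNA1H. The run tags in the sample titles differed between S4 and S5, so run and culture could not be told apart.

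H1 cells served as the pluripotent reference. With all lists shortened to the length of the H1 list, 16.6% ± 1.83 of the 25215 H1 regions were called in the 2D libraries (SD, n = 2), 13.5% ± 0.278 in the primary libraries, 15.2% in S4 and 14.8% in S5. These shares depended on list length: with the lists as deposited they were 39.5% in 2D and 35.2% in primary libraries, with equal numbers of peaks 35.7% and 33.3%, and with 50% coverage 3.48% and 2.70%. In turn, of 4384 primary regions at this length, 74.7% ± 7.79 were called in the 2D libraries, 65.8% in S4, 72.7% in S5 and 69.5% in H1, but H1 called 25.5% with the lists as deposited. Peaks at a gene end were called for 11 of 16 pluripotency genes in H1, against 0 and 0 in the primary, 0 and 1 in the 2D, 1 in the S4 and 0 in the S5 library. At this length H1 had a peak at more gene ends of all kinds, 7911 of 19975 against 4864 to 5938, and at 8 of 12 proliferation genes against 0 or 1. With the lists as deposited, 9 and 6 pluripotency genes were called in the primary libraries, 8 and 13 in the 2D libraries, 9 in S4 and 7 in S5. Those longer lists also called more gene ends of all kinds, 13112 to 15973 of 19975 against 7911 in H1. The raw counts therefore cannot show whether H1 stood apart. NANOG, a core pluripotency factor, had 2.98 kb in H1 and no peak in the other libraries, and SOX2 had 9.69 kb. The loci with the largest H1 excess over 2D cells were CHN1, LIN28B, CLYBL, WDPCP, ZMYND8, RBPMS, VRTN and FOXN3, and LIN28B had 12.2 kb in H1. The largest deficits were at H19 and its neighbour MRPL23, DUS1L, GPS1, DENND6B, PLXNB2, RFNG and ALYREF. Against a median of -0.54 for all genes, the endoderm (-2.17), hepatocyte factor (-2.05), plasma protein (-1.49) and thyroid hormone (-1.26) lists lay below the 1st percentile of random lists, and the pluripotency (0.61) and fetal-liver (0.38) lists lay above the 99th. Only 4 of 16 pluripotency genes had enough cover, of which 2 were higher and 2 lower. The other medians also rested on part of each list: 3 of 10 endoderm, 8 of 15 hepatocyte factor and 3 of 21 plasma protein genes. For the thyroid hormone and fetal-liver lists these were 6 of 12 and 7 of 12 genes. H1 peaks were narrow, so covered lengths in H1 were not on the footing of the other libraries.

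Calls at gene ends gave a second view of the lists. Of 19 drug oxidation genes, 7 and 8 had a peak within 1 kb of a gene end in the primary libraries, 1 and 1 in the 2D libraries, 2 in S4 and 3 in S5; with the lists as deposited the 2D libraries had 3 and 3, S4 had 4 and the others were unchanged. Of 14 endothelial genes none was called in the primary libraries, 4 and 3 in the 2D libraries and 1 in each 3D library; as deposited these were 1 and 0, 6 and 8, and 2 and 4. All 14 housekeeping genes were called in each of these 6 libraries. By this measure 8 lists lay higher in both primary libraries than in both 2D libraries and 5 lay lower. With the lists as deposited, 2 lists, acute phase and drug oxidation, lay higher and 7 lower.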

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

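All tests weighed here were chosen after the results they concern had been seen. Set against each 2D library in turn, S4 lay below and S5 above in 4 measures. The difference between S4 and S5 was not tested in any of them. The rule was applied in either direction to the medians of the 29 lists and to the shares of primary and 2D regions. No other measure met it. Some can meet it by chance, so the number that did shows no consistent pattern. S4 and S5 called 51.5% and 65.0% of the primary regions, and 7.09% and 22.4% of the primary regions missing in 1 of the 2D libraries (mean of both choices). For the latter, S5 exceeded the other 2D library by only 0.617 percentage points in one choice and by 6.39 in the other. The median of the urea and amino acid list differed from the 2D mean by -0.0498 in S4 and 0.439 in S5, and that of the conjugation enzyme list by -0.0547 and 0.278. The S4 medians were unremarkable among random lists (percentiles 28.7 and 37.8), and relative to all genes they turned to 0.0333 and 0.267 with the lists as deposited and 0.0852 and 0.254 after scaling.

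S4 called fewer primary regions than either 2D library. Weak peaks in the S4 list stay open: at the length of the H1 list S4 was still 3.38 percentage points below the lower 2D library (a difference of -3.38), but the SD of the 2D shares there was 7.79. A candidate explanation is more gut-like and bile-duct-like acetylation in S4. For S5 minus S4 the cholangiocyte list lay at percentile 0.11 and the intestine list at percentile 0.3 of random lists, but the hypoxia list lay at percentile 0.33. KRT19 had 20.3 kb and CDH17 8.29 kb in S4. KRT7, of the bile-duct list, went the other way, with no peak in S4, 3.02 kb in S5 and 2.15 kb on average in 2D cells. These percentiles set S4 against S5 rather than 2D cells. They were not linked to the primary regions that S4 lacked, so they cannot decide the explanation. The hepatocyte factor list was also high in S4, and the bile-duct and intestine lists lay above the 2D mean in S5 too. Another sequencing run for S4 cannot be told apart from the culture condition, because 0 groups had libraries in both runs. The culture condition itself was not tested.

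The 2D libraries overlapped each other (0.504) less than each overlapped S5 (0.578 and 0.571). Differences in weaker peaks may contribute: at the length of the H1 list the 2D pair reached 0.601, between the pairs with S5 at 0.593 and 0.635, so the order was no longer clear. A mesenchymal-like part of one 2D library was left open, with the stellate and mesenchymal list at percentile 93.3 for 2D replicate 1 minus 2D replicate 2. The labels name no biological difference between the 2D libraries, so none was tested.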

How the results depend on the processing

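The score of at least 200 and the gene-body and deposited versions of the gene-end calls were chosen after seeing the data. Counts of loci higher and lower in primary hepatocytes (346 and 477) stayed within 1.5 times with a score of at least 200 (510 and 626), 5-kb flanks (505 and 569), 100-kb flanks (352 and 495), a pseudocount of 0.2 kb (410 and 581), no filter (282 and 318) and all 7 libraries in one fit (257 and 342). The loci themselves changed more: of the 346 and 477, 134 and 207 were called again with 100-kb flanks, 201 and 322 with 5-kb flanks, 188 and 274 without the filter, 306 and 414 with a score of at least 200, and 326 and 448 with the smaller pseudocount. The counts were 3 and 251 as deposited, 33 and 202 after scaling, and 0 to 1713 and 0 to 1540 with a replicate left out, where the lone library was assumed to vary like the others. For 3D against 2D cells no filter gave 11 and 19, and the other settings 0. With an estimated correlation 0 of the 10 higher and 0 of the 4 lower lists passed.

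As deposited, primary-only regions numbered 3158 and 2D-only regions 18917, and in 500-bp bins 17339 and 9905. With a replicate left out they numbered 11396 to 15667 and 4008 to 12729, under a looser definition that by itself raises the counts. The 2D share of primary regions was 80.2% as deposited, 54.9% with 50% coverage and 51.4 to 63.2% with a replicate left out. The share in S4 was 60.8% as deposited, 52.1% with equal numbers of peaks, 54.1% with a score of at least 200, 46.5% with 50% coverage and 43.7 to 51.3% with a replicate left out, and that in S5 72.6%, 67.2%, 66.8%, 60.7% and 56.5 to 64.9%. S5 was above the 2D mean in each of these settings except as deposited. The share in H1 was 25.5% as deposited, 32.3% with equal numbers, 65.3% with a score of at least 200, 11.8% with 50% coverage and 67.2 to 69.5% with a replicate left out. Of primary regions missing in 1 2D library, the other 2D library called 44.4% and S4 10.5% as deposited, and S4 5.88 to 6.86% with a replicate left out. Of 2D regions missing in primary hepatocytes, S5 called 23.4% as deposited.

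For regions of S5 and not S4, the share in both primary libraries was 26.7% as deposited, 33.9% with equal numbers, 33.6% with 50% coverage and 37.6 to 45.1% with a replicate left out. For regions of S4 and not S5 it was 0.900% as deposited, 1.07% with equal numbers, 1.90% with a score of at least 200 and 1.59 to 2.52% with a replicate left out. H1 regions were called at 39.5% in 2D and 35.2% in primary libraries as deposited, at 35.7% and 33.3% with equal numbers, and at 3.48% and 2.70% with 50% coverage. The overlap of the 2D libraries was 0.401 as deposited; an overlap counted as unchanged within 0.05. Gene-end calls in 2D libraries averaged 2.5 in gene bodies and 3 as deposited for drug oxidation, and 6 and 7 for the endothelial list.

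For the named loci past the threshold for primary against 2D cells, 219 of 453 alternative values stayed past it, 233 lost it and 1 reversed, POU5F1 with 5-kb flanks (-0.23). Of 362 values of loci that did not pass, 38 passed and 11 changed sign. Of 339 values for 3D against 2D, none passed and 7 changed sign. The planned threshold on q and the motif comparison were not run. Peak depth was unknown, which limits every count of regions. Causes of these changes were not tested.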

Other observations

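The first of the 2 tests in the last paragraph was set before its result was seen, and the second after. Regions called in S4 alone of the 6 hepatocyte libraries numbered 10222, against 2890 in S5 alone, 6124 and 4771 in the 2D and 2668 and 4478 in the primary libraries. Regions called in S4 and S5 and in none of the other 4 libraries numbered 1341, and the longest, 6431 bp on chromosome 17 from 45408220 to 45414650, overlapped ARHGAP27. A further 1154 regions were called in both primary libraries and S5 but in neither 2D library nor S4. The longest of these, 8936 bp on chromosome 2 from 232441500 to 232450435, lay 5717 bp from ALPI, the intestinal alkaline phosphatase gene.

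The 2D libraries differed from each other at single loci. HOXB4 had 18.4 kb in 2D replicate 1 and 0.977 kb in 2D replicate 2, and HOXB5 had 17.8 and 1.68 kb. CYP26B1 had no peak and 14.1 kb, and HGFAC, the hepatocyte growth factor activator, had no peak and 12.4 kb. For 2D replicate 1 minus 2D replicate 2, the acute phase list lay at percentile 99.3 of random lists (median 0.75), the fetal-liver list at 99.2 (0.43), the pluripotency list at 98.3 (0.25), the AP1 and YAP list at 97.9 (0.37) and the neural list at 0.75 (-0.80). These differences were not tested.

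Some genes known for high activity in liver had little cover in primary hepatocytes: ALB had 0.954 kb, and CYP3A4 and CYP7A1 had no peak at their loci. Plasma protein genes as a list showed no deficit, with a median of 2.15 kb against 2.10 kb for all genes, at percentile 58.1 of random lists matched on the number of genes within 500 kb, so the first test decided nothing. Drug oxidation genes had a median of 0.781 kb, at percentile 0.35 of such lists, and 7 of 19 had no cover. They did not lie in sparse gene neighbourhoods as a list, with a median of 18 genes within 500 kb against 13 for all genes. The random lists drew genes singly, so cover shared between neighbouring loci was not matched and the percentile may be too extreme. Hepatocyte factors had a median of 10.6 kb (percentile 100), JAK-STAT3 genes 7.73 kb (99.9), AP1 and YAP targets 5.13 kb (99.8), apolipoproteins 4.83 kb (99.3) and urea and amino acid genes 4.19 kb (99.6). Bias of the libraries by base composition was not tested, because no genome sequence was used here.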
